A study of Mus musculus with 12 samples.

How the data were processed

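Gene expression was measured in livers of 12 male mice, 3 per group, on Affymetrix arrays. The labels give 4 groups: untreated wild-type mice, and wild-type, PPARα-null and Clk/Clk mutant mice fed bezafibrate. Bezafibrate was given at 0.5% (w/w) in the diet for 5 days. The mice were 6 to 12 weeks old and were kept under 12 h light and 12 h dark. Livers were taken at ZT14, and 250 ng of total RNA per liver was labelled for hybridization. Wild-type and Clk/Clk mice were of the Jcl:ICR strain per the labels, and the null mice came from a 129S4SvJae-derived line crossed with Jcl:ICR. The labels give no array date or batch. No mutant was left untreated, so the difference of a mutant's genotype and the difference of its response to the drug are not separated.

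The deposited values are log2 expression values per probe set. The authors name RMA for processing, a method that corrects background, equalises the arrays and summarises probes, without giving its version or settings. All 12 columns of values were used. The values ran from 2.25 to 15.0, and the medians of the 12 arrays lay between 5.45 and 5.50, so the arrays had been equalised together. On arrays no sequencing depth exists; precision is limited by the 3 mice per group and, for weak genes, by signal near background. Over all probe sets except array controls, pairs of arrays within a group correlated at 0.993 to 0.996. Pairs from different groups correlated at 0.969 to 0.990, and genes are not independent replicates. The median residual SD of a gene was 0.124 on the log2 scale, with 8 residual degrees of freedom.

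Of 45101 probe sets, 64 were array controls. Of the other 45037, the platform's gene table gave exactly 1 symbol to 34945, several to 932 and none to 9160. Symbols were matched through gene identifiers to a reference gene table (GRCm38.p6), used for names and gene order only, and no symbol changed. The 204 probe sets without a match kept the platform's symbol. Probe sets were kept when they reached the 40th percentile of their array on at least 3 arrays, a level of 4.87 to 4.92. That left 28344 probe sets, of which 23888 had 1 symbol. Each gene was represented by its probe set with the highest mean over the 12 arrays, giving 13598 genes. Probe sets without exactly 1 symbol entered no gene comparison and are described in the closing section.

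The arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 4 group means and no covariate. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05 and its difference was at least 1.5-fold. The main comparisons were bezafibrate against no treatment in wild type, PPARα-null against wild type on bezafibrate, and Clk/Clk against wild type on bezafibrate. The remaining contrasts between the 4 groups were secondary. A joint set held genes called higher with bezafibrate and lower in both mutants, and its mirror held the opposite calls. Since all 3 main comparisons use the treated wild-type arrays, overlaps were set beside those of independent lists and beside 20 simulations in which both mutants equal treated wild type.

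30 gene lists were written from general knowledge, covering lipid, bile acid, amino acid and sugar metabolism, clock genes, stress and immune responses, cell cycle, sex-dependent genes and cell type markers. Each list was tested with camera (preset correlation between genes 0.01), adjusted over the 30 lists of a comparison. Camera asks whether a list's genes move more one way than other genes do. The tests were repeated with an estimated correlation and with fry, which asks whether a list moves one way on balance without comparing it with other genes. A list score per mouse was the mean over its genes of the log2 value minus the untreated wild-type mean; scores were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Genes near Ppara and Clock (the 200 nearest tested genes, also 100 and 400) were compared with all others by Fisher's exact test.

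Genes are named by a rule. Per main comparison it takes the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and from each list up to 4 genes with the smallest adjusted p. From the joint set and its mirror it takes the 15 with the largest mean absolute change. It always takes Ppara, Clock, Arntl, Npas2, Per1, Per2, Per3, Cry1, Cry2, Nr1d1, Nr1d2, Dbp, Cyp4a14, Ehhadh, Cpt1a, Pdk4, Angptl4, Fgf21, Cyp7a1 and Cyp2b10. Cyp4a10 also belongs to it but had no probe set with exactly 1 symbol, so it is not analysed here. The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined. Counts of called list members with an array left out were added afterwards.

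The pipeline was tested on simulated data with known changes at 1.5-fold and 2-fold in 67 genes each and at 4-fold in 66, of 13598 genes. For bezafibrate in wild type 37.3%, 88.1% and 98.5% of the changed genes were recovered at these folds, for PPARα-null mice 37.3%, 92.5% and 100%, and for Clk/Clk mice 32.8%, 95.5% and 98.5%. At 1.5-fold the fold threshold itself removes genes, and by adjusted p alone 61.2%, 71.6% and 74.6% were recovered. Unchanged genes called numbered 3, 2 and 3. Noise was drawn independently per gene, so these counts do not cover correlation between genes. The 3' minus 5' differences of the Gapdh and Actb control probe sets were compared between groups as a sign of RNA quality. Exact two-sided permutation p was 0.4, 1 and 0.5 for Gapdh and 0.2, 0.1 and 0.6 for Actb, in the order of the main comparisons, with 0.1 the smallest possible. Actb was at 1.15 (SD 0.0503) in null and 1.29 (SD 0.0755) in treated wild-type mice without overlap, so a difference in RNA quality between these groups is not excluded.

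Alternatives were: no filter or a filter at the 60th percentile, quantile normalization or median centring on top of the deposited values, the mean of a gene's probe sets, leaving out probe sets with the suffixes _s_at, _x_at or _a_at, fitting only the groups compared, eBayes with trend and robust settings, array weights, replicate number as a block, leaving out each array in turn, no fold threshold, a 2-fold threshold, limma's treat against 1.5-fold, and the list tests above. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.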

Results

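The study asks which genes that the nuclear receptor PPARα regulates in liver also depend on the clock protein CLOCK. Ppara and Clock were examined first. The brightest Ppara probe set read 11.56 (SD 0.253) in untreated wild type and 10.78 (SD 0.232) in treated wild type, on the log2 scale. It read 9.88 (SD 0.157) in treated PPARα-null mice, so transcript signal persisted there, at -0.90 (SE 0.142, adjusted p = 5.74e-04) from treated wild type. Clock signal on its brightest probe set was 8.17 (SD 0.282) in treated wild type and 9.25 (SD 0.162) in Clk/Clk mice, a difference of 1.08 (SE 0.159, adjusted p = 8.26e-04). The Ppara value was lower in the null group on all 3 of its probe sets, and the Clock mean was higher in Clk/Clk mice on all 4, by the least on the dimmest (5.65, SD 0.323, against 5.58, SD 0.137). Where these probe sets lie relative to the disrupted exon or the mutation is not given in the sources used here, so these values check neither genotype.

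Bezafibrate changed 2798 of 13598 genes in wild-type liver, 1742 higher and 1056 lower (n = 3 per group). The largest rise was in Pdk4, a kinase that limits glucose oxidation, by 7.32 on the log2 scale (SE 0.365, 160-fold, adjusted p = 6.42e-08). Pctp, a phosphatidylcholine carrier, rose by 6.78 (SE 0.2), Mogat1, a triglyceride-synthesis enzyme, by 5.82 (SE 0.233), and the fatty acid transporter Cd36 by 4.95 (SE 0.101). The largest fall was in Hsd3b5, a male-predominant steroid dehydrogenase (-7.40, SE 0.416, 168-fold, adjusted p = 1.48e-07). The cytochromes Cyp2c50 (-6.84, SE 0.516) and Cyp2c54 (-6.65, SE 0.33) followed. Pck1, a gluconeogenic enzyme, fell by 4.66 (SE 0.347), and Cyp7a1, which starts bile acid synthesis, by 4.59 (SE 0.65). Other large rises were in Vnn1 (5.80), Fabp3 (5.73), Ly6d (5.72), Acot2 (5.32), Cyp4a14 (5.07), Fabp4 (4.81), Cox6b2 (4.76) and Cbr3 (4.61). Other large falls were in Fam47e (-4.84), Hsd3b2 (-4.58), B3galt1 (-4.44), Cyp4f14 (-4.35) and Pigr (-4.29), while Fam107a and Hectd2os (each -5.19) dropped under the filter level. Members of the Cyp2c, Cyp4a, Hsd3b and Acot families are similar in sequence, and their probe sets may share signal. The treated means of Cyp2c54 (4.58) and Fam47e (4.64) and the untreated mean of Mogat1 (4.74) also lay under the filter level, and treated Cyp4a14 (14.25) near the top of the scale, so these folds are not exact.

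The classical PPARα programme of fatty acid oxidation was higher in treated wild type. Of 31 tested peroxisomal genes 20 rose and 2 fell (mean 1.03, camera adjusted p = 3.26e-07; adjusted p = 0.0423 with an estimated correlation). Ehhadh rose by 2.60 (SE 0.127), a lower bound if its treated signal of 14.41 was saturated, Pex11a by 2.15 (SE 0.094), Acot8 by 2.09 (SE 0.0872) and Crot by 1.55 (SE 0.0661). In the mitochondrial fatty acid oxidation and ketogenesis list 17 of 25 genes rose and none fell (mean 1.62, adjusted p = 2.48e-13; adjusted p = 0.0597 with an estimated correlation). They included Acot1 (4.15), Slc22a5 (2.87), Eci1 (2.22) and the hormone Fgf21 (3.20, SE 0.323), whereas Cpt1a differed by 0.17 (adjusted p = 0.271). Among fatty acid uptake and lipid droplet genes 23 of 29 rose and none fell (mean 1.69, adjusted p = 2.91e-11; adjusted p = 0.0106 with an estimated correlation). Vldlr rose by 3.57, Plin2 by 2.29 and Angptl4 by 0.88 (SE 0.0956). The microsomal omega-oxidation list divided into 4 rises, such as Aldh3a2 (3.03), and 3 falls, such as Adh4 (-1.41), and its test gave adjusted p = 0.338.

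Lipid synthesis was higher as well. In lipogenesis 15 of 25 genes rose and 2 fell (mean 0.999, adjusted p = 2.52e-04; adjusted p = 0.159 with an estimated correlation), with Me1 at 2.92, Acacb at 2.32 and Acaca at 1.48. In cholesterol synthesis 15 of 20 genes rose and none fell (mean 1.40, adjusted p = 5.28e-05; adjusted p = 0.436 with an estimated correlation), among them Fdps (2.83), Pmvk (2.45), Hmgcs1 (2.44) and Hsd17b7 (1.25). DNA replication and cell cycle genes gave 19 rises and no fall among 26 (mean 1.67, adjusted p = 1.79e-06; adjusted p = 0.348 with an estimated correlation). Mcm5 rose by 3.87 (SE 0.445), Ccnd1 by 3.16 (SE 0.237), Mcm2 by 2.83 (SE 0.328) and the cell cycle inhibitor Cdkn1a by 2.46 (SE 0.287). Of 20 NRF2 antioxidant genes 11 rose and 2 fell (mean 1.19, adjusted p = 0.00469; adjusted p = 0.546 with an estimated correlation), with Abcc4 at 4.04, Srxn1 at 2.66 and Gstm4 at 2.14; the 2 falls became 1 without treated mouse 1 or untreated mouse 2. Type I interferon genes gave 11 rises among 19 (mean 1.15, adjusted p = 0.0103; adjusted p = 0.6 with an estimated correlation), led by Usp18 (2.76), Rsad2 (2.71) and Cxcl10 (2.59). The interferon call was lost at the 60th-percentile filter (adjusted p = 0.0515), and the scores of the 3 treated mice were 1.85, 1.11 and 0.475. The respiratory chain list had a mean of 0.19 (adjusted p = 0.0158; adjusted p = 0.577 with an estimated correlation) and 1 rise among 27, citrate synthase Cs (1.55). That call was lost without treated wild-type mouse 2 (0.0532), untreated mouse 1 (0.0695) or suffix probe sets (0.0768).

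Secreted and metabolic hepatocyte genes were lower. In complement and coagulation 22 of 28 genes fell and none rose (mean -1.29, adjusted p = 1.56e-16; adjusted p = 0.0106 with an estimated correlation). F7 fell by 1.87 (SE 0.0955), Masp1 by 1.80, Klkb1 by 1.74 and F13b by 1.09. Amino acid catabolism and urea cycle genes gave 24 falls and no rise among 30 (mean -1.18, adjusted p = 3.06e-15; adjusted p = 0.0597 with an estimated correlation), such as Hal (-2.70), Otc (-1.85) and Fah (-1.46). Gluconeogenesis and glycogen genes gave 11 falls and 2 rises among 17 (mean -0.83, adjusted p = 1.24e-04; adjusted p = 0.0624 with an estimated correlation), with Ppp1r3c at -2.97 and Slc37a4 at -2.06. In the bile acid list 12 of 22 fell and 2 rose (mean -1.05, adjusted p = 3.26e-06; adjusted p = 0.0597 with an estimated correlation), including Akr1d1 (-3.06), Slco1a1 (-2.31), Slc10a1 (-1.46) and Baat (-0.99). Acute phase genes gave 15 falls and no rise among 28 (mean -1.05, adjusted p = 1.96e-05; adjusted p = 0.348 with an estimated correlation), with Saa4 at -3.42 and Crp at -1.75; there were 2 rises without treated mouse 2, and 1 without treated mouse 3 or untreated mouse 1. The lipoprotein list had 6 falls, such as Apom (-1.29), and 3 rises, such as Pltp (3.45), among 20 (mean -0.18, adjusted p = 0.01; adjusted p = 0.0597 with an estimated correlation).

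Male-predominant genes and genes of growth hormone signalling were lower in treated wild type. Of 13 male-predominant genes 9 fell and 1 rose (mean -1.70, adjusted p = 3.87e-05; adjusted p = 0.0597 with an estimated correlation), with Cyp7b1 at -2.56 and Cyp2u1 at -1.09 beside Hsd3b5. In the growth hormone list 9 of 12 fell and 2 rose (mean -1.14, adjusted p = 8.15e-04; adjusted p = 0.0597 with an estimated correlation), including Egfr (-3.47), Igfals (-1.76), Ghr (-1.30) and Igf1 (-1.08). The 2 rises in this list became 1 without untreated mouse 1, and the 1 rise among male-predominant genes was lost without treated mouse 1 or untreated mouse 2 or 3. Female-predominant genes gave 6 rises, among them Cyp2b9 (3.61), Acot3 (3.36), Cyp2b13 (2.72) and Cyp17a1 (1.05), and 3 falls among 14; the median was -0.01, the mean 0.79 and the adjusted p 0.528. Clock output genes gave 7 falls and no rise among 16 (mean -0.61, adjusted p = 0.0051; adjusted p = 0.33 with an estimated correlation). Cry1 fell by 1.497 (SE 0.164), Per1 by 1.32 (SE 0.214), Hlf by 0.72 and Cry2 by 0.67. Per2 (-0.52), Per3 (-0.23), Dbp (-0.99), Nr1d1 (0.27) and Nr1d2 (-0.42) did not pass. In the positive limb Nfil3 (-1.91) and Arntl (-0.73, SE 0.2) passed, the latter not without treated wild-type mouse 2 (-0.58), with the mean of its probe sets (-0.57) or with suffix probe sets left out (-0.41). Npas2 was at 0.39, Clock at 0.36 and the list of 4 at adjusted p = 0.557.

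CAR and PXR genes divided into 4 rises and 6 falls among 20 (adjusted p = 0.324), with Cyp2b10 at -2.40 and Cyp2c37 at -3.12, the latter under the filter level after treatment. Heat shock and cold-inducible genes, tested together, had 3 rises among 14, led by Hspb1 (2.60), and a list adjusted p of 0.0672. It was 0.0305 without untreated mouse 1, 0.0324 without untreated mouse 3 and 0.022 with no filter. With the mean of a gene's probe sets it was 0.042, and with the replicate block 0.0476. ER stress genes had 4 rises and 5 falls among 21, with Herpud1 at -1.80; their median was -0.45, their mean 0.05 and their adjusted p 0.156. The 5 falls became 2 without untreated mouse 1, 3 without treated mouse 2 and 8 without untreated mouse 2, and the list's adjusted p was 0.0273 in the last case. Sinusoidal endothelial markers fell as a list (4 of 15 called, Stab2 at -0.86; mean -0.33, adjusted p = 0.00675; adjusted p = 0.366 with an estimated correlation), with 1 call left without treated mouse 1. Macrophage markers had 1 rise (Cd68, 0.90) and 1 fall (Ccr2, -0.74, or -0.27 and not passing as the mean of its probe sets) among 17 (adjusted p = 0.928), with median 0.05 and mean 0.06 but a test pointing down. The 1 rise became 2 without treated mouse 2, 3 without treated mouse 3 and 2 without untreated mouse 1, where there were also 2 falls. Stellate markers had 4 falls among 17 (median 0.09, mean -0.17, adjusted p = 0.313), with Hand2 at -1.16. Cholangiocyte markers had 3 rises among 6, with Krt23 at 4.09 (adjusted p = 0.17, or 0.0446 with the mean of a gene's probe sets and 0.0445 without suffix probe sets), blood cell markers 3 falls among 13 (0.329) and carry-over markers 1 rise among 6, Pnliprp1 at 2.47 from a level under the filter (0.426). Adjusted over the list alone, the counts of called genes were the same for all 30 lists.

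**Figure D1:**
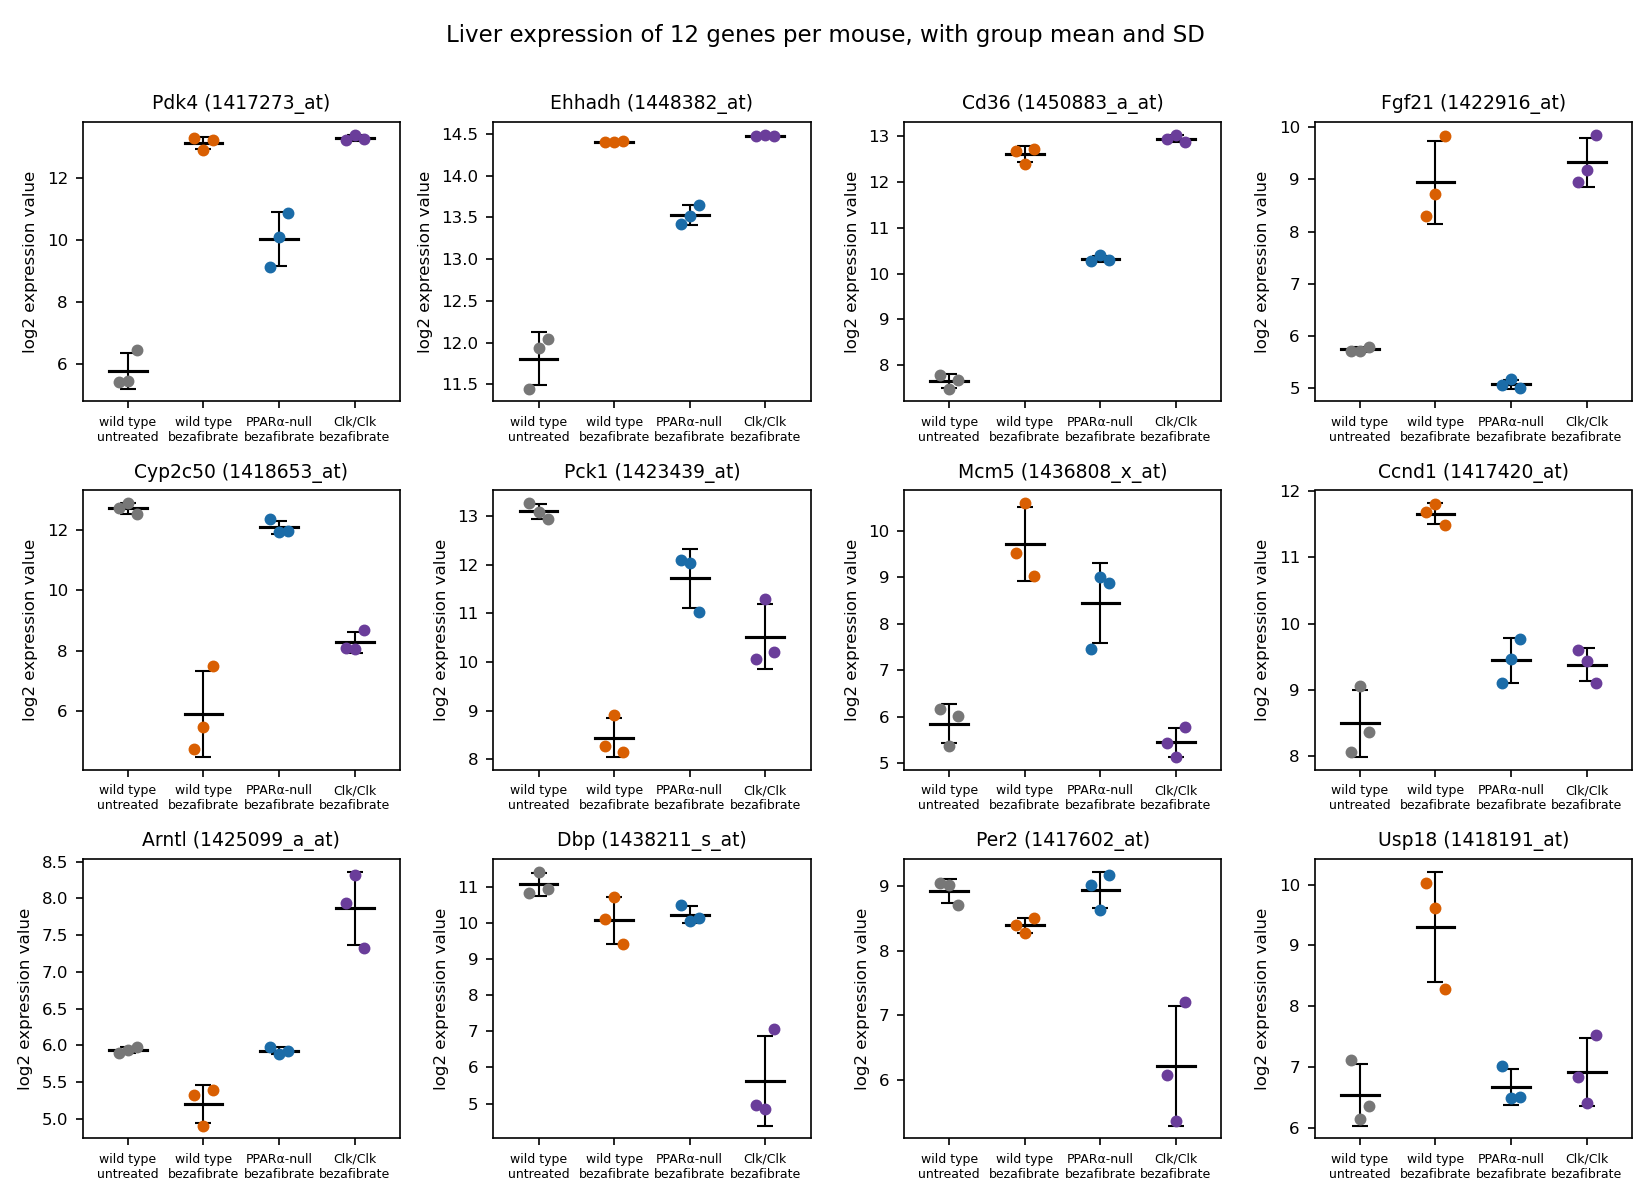
Log2 expression values (y axis) of 12 genes in the 4 groups (x axis), one point per mouse, with bars at the group mean and SD (n = 3); the genes were chosen for display after their values were seen. Pdk4 stood at 10.02 in PPARα-null mice, between untreated (5.80) and treated wild type (13.12), and Dbp stood at 5.63 in Clk/Clk mice against 10.08 in treated wild type.

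On bezafibrate, PPARα-null livers differed from wild-type livers in 1827 genes, 727 higher and 1100 lower, mostly opposite to the drug response. Of the 1742 genes that rose with the drug in wild type, 901 (51.7%) were lower in null mice, where independent lists would share 141; of the 1056 that fell, 545 (51.6%) were higher, against 56.5. Only 5 and 6 genes went the same way in both comparisons, against 93.1 and 85.4. The largest differences downwards were in Ly6d (-5.58, SE 0.204, 47.8-fold), Fabp3 (-5.51), Hao2 (-5.36), Abcd2 (-4.95), Cyp2b9 (-4.89), Serinc2 (-4.73), Cox6b2 (-4.64), Cbr3 (-4.43), Rad51b (-4.38) and Mogat1 (-3.90). Hao2 and Abcd2 read under the filter level in the null group. The largest differences upwards were in Hsd3b5 (6.43, SE 0.416, 86.5-fold), Cyp2c50 (6.21), Cyp2c54 (5.76), the bile acid and drug transporter Slco1a4 (4.95), Pbld1 (3.61), Cyp7a1 (3.52, SE 0.65, adjusted p = 0.0016), Nox4 (3.45), Ces2a (3.40), Mup10 (3.36) and Pck1 (3.28). Fgf21 was lower by -3.88 (SE 0.323) and Pdk4 by -3.10 (SE 0.365).

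The fatty acid lists were lower in null mice. Peroxisomal genes gave 21 of 31 lower and 2 higher (mean -0.99, adjusted p = 1.64e-11; adjusted p = 0.00923 with an estimated correlation), such as Acot8 (-2.26), Pex11a (-1.94) and Amacr (-1.68); adjusted over the list alone 22 were lower. The 2 higher became 1 without null mouse 1 or 3 or treated wild-type mouse 3. Mitochondrial oxidation genes gave 18 of 25 lower and none higher (mean -1.08, adjusted p = 4.92e-16; adjusted p = 0.046 with an estimated correlation), such as Cpt2 (-1.38), Etfdh (-1.35), Acadvl (-1.34) and Hadhb (-1.02). Uptake and lipid droplet genes gave 21 of 29 lower and none higher (mean -1.28, adjusted p = 1.19e-11; adjusted p = 0.00923 with an estimated correlation), with Vldlr at -3.08, Fitm1 at -2.31, Cd36 at -2.28 and Plin2 at -1.31. Of the genes always named, Ehhadh was at -0.88, and Angptl4 (-0.46) and Cpt1a (0.08) did not pass. Cyp4a14 was at -1.23 (SE 0.429, adjusted p = 0.0451) and missed the threshold without null mouse 1 (-0.90) or 2 (-1.31) or treated wild-type mouse 1 (-1.24), 2 (-1.24) or 3 (-1.20), and with array weights (-1.14) or robust settings (-1.23). Ehhadh and Cyp4a14 read near the top of the scale in treated wild type, so these differences are lower bounds if the signal was saturated. Omega-oxidation genes had 2 higher, such as Cyp4f14 (3.22), and 3 lower among 11, such as Aldh3a2 (-1.92; list adjusted p = 0.434). The 3 lower became 1 without null mouse 2, and the 2 higher became 1 without null mouse 1 or treated wild-type mouse 1.

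Several lists of metabolic and secreted hepatocyte genes were higher in null mice. Complement and coagulation genes gave 19 of 28 higher and none lower (mean 0.98, adjusted p = 9.64e-16; adjusted p = 0.00923 with an estimated correlation), with Klkb1 at 1.29, F7 at 1.25 and F13b at 0.99. Amino acid genes gave 17 of 30 higher and none lower (mean 0.84, adjusted p = 2.35e-10; adjusted p = 0.087 with an estimated correlation), with Oat at 3.20, Asl at 2.04 and Hal at 1.84. Gluconeogenic genes gave 9 of 17 higher and 2 lower (mean 0.61, adjusted p = 6.26e-04; adjusted p = 0.0977 with an estimated correlation); the 2 lower became 1 without null mouse 1 or 3 or treated wild-type mouse 1 or 3. Bile acid genes gave 12 of 22 higher and 1 lower (mean 1.04, adjusted p = 1.63e-06; adjusted p = 0.066 with an estimated correlation), including Akr1d1 (2.85), Slco1a1 (2.07) and Slc10a1 (1.68); adjusted over the list alone 13 were higher. Male-predominant genes gave 8 of 13 higher and none lower (mean 1.49, adjusted p = 2.62e-06; adjusted p = 0.0517 with an estimated correlation), and growth hormone genes 7 of 12 higher and 1 lower (mean 0.96, adjusted p = 6.33e-04; adjusted p = 0.0585 with an estimated correlation). Nat8 (2.19), Igfbp3 (1.86), Igfals (1.74) and Egfr (2.89) were among them. The 1 lower growth hormone gene stayed called only without treated wild-type mouse 1. Lipoprotein genes had 4 higher and 2 lower among 20 (mean 0.22, adjusted p = 0.0381; adjusted p = 0.105 with an estimated correlation); the call was lost without null mouse 1 (0.0559) or suffix probe sets (0.0645), with the mean of a gene's probe sets (0.12) and with quantile normalization (0.111). CAR and PXR genes had 9 of 20 higher and 2 lower (mean 0.98, adjusted p = 0.00164; adjusted p = 0.213 with an estimated correlation), with Cyp2c55 at 3.19 and Cyp2b10 at 2.19.

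Clock, growth and immune lists also differed between null and wild-type mice on bezafibrate. Clock output genes had 3 higher and none lower among 16, namely Usp2 (1.43), Cry1 (0.80) and Hlf (0.75), with a mean of 0.35 (adjusted p = 0.0381; adjusted p = 0.526 with an estimated correlation). That call was lost without null mouse 1 (0.0559) or treated wild-type mouse 1 (0.0551) or 3 (0.0694), without suffix probe sets (0.0724) and with quantile normalization (0.0552). Arntl was at 0.72 (not passing without treated wild-type mouse 2 at 0.57, as the mean of its probe sets at 0.56 or without suffix probe sets at 0.41) and Nfil3 at 1.24, while the positive limb list had adjusted p = 0.434; Per1 (0.45), Per2 (0.54), Per3 (0.21), Dbp (0.14), Nr1d1 (-0.19) and Nr1d2 (-0.03) did not pass. Cell cycle genes gave 9 of 26 lower and none higher (mean -0.62, adjusted p = 0.00898; adjusted p = 0.682 with an estimated correlation), with Ccnd1 at -2.21, Cdkn1a at -1.76 and Mcm2 at -1.41; adjusted over the list alone 10 were lower. That list call was lost without null mouse 1 (0.089) or treated wild-type mouse 2 (0.162). Their scores overlapped between the groups (exact two-sided permutation p = 0.3). The count of 9 became 4 without either of these arrays, 5 without treated wild-type mouse 1 and 13 without treated wild-type mouse 3. Interferon genes gave 11 of 19 lower and none higher (mean -1.04, adjusted p = 0.00164; adjusted p = 0.682 with an estimated correlation), with Usp18 at -2.64 and Rsad2 at -2.29. NRF2 genes had 8 of 20 lower and 1 higher (mean -0.56, adjusted p = 0.0381; adjusted p = 0.682 with an estimated correlation), a call lost without null mouse 1 (0.0991) or treated wild-type mouse 2 (0.0921) or 3 (0.0997), or with a filter at the 60th percentile (0.0883); the 1 higher became 2 without treated wild-type mouse 3. Heat shock and cold-inducible genes had 3 of 14 lower (mean -0.52, adjusted p = 0.00618, and adjusted p = 0.44 with an estimated correlation), led by Hspb1 (-3.13). That list did not pass without suffix probe sets (0.0518).

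Lipogenesis had 3 higher and 5 lower among 25 (adjusted p = 0.176, and 0.0463 without treated wild-type mouse 3), with Scd2 at -2.58 and Pklr at 2.05; adjusted over the list alone 4 were higher. Cholesterol synthesis had 6 of 20 lower (adjusted p = 0.122, and 0.0455 with no filter on low values), with Hmgcs1 at -1.34 and Pmvk at -1.17. The count of 6 became 3 without null mouse 1 or treated wild-type mouse 1 or 2. Acute phase genes had 8 higher and 1 lower among 28 (adjusted p = 0.0535), with Saa4 at 2.68 and Crp at 1.68; adjusted over the list alone 2 were lower. The acute phase value passed without null mouse 2 (0.0448) or 3 (0.0305) or treated wild-type mouse 1 (0.0038), with arrays centred on their median (0.0442), a filter at the 60th percentile (0.0332) or the replicate block (0.0276). The 1 lower acute phase gene became 4 without null mouse 1, 3 without treated wild-type mouse 2 and 2 without treated wild-type mouse 3, and none was left without null mouse 2 or treated wild-type mouse 1. Female-predominant genes had 1 higher and 5 lower among 14 (adjusted p = 0.157), with Cyp2b13 at -3.15. ER stress genes had 2 calls each way among 21 (adjusted p = 0.517), with 1 higher without null mouse 3 or treated wild-type mouse 2. Cell type lists did not pass, with adjusted p of 0.801 for macrophages, 0.259 for endothelium, 0.693 for stellate cells, 0.322 for cholangiocytes, 0.674 for blood cells and 0.451 for carry-over markers. Krt23 was at -3.79 and Pnliprp1, under the filter level in null mice, at -2.82. The macrophage median was 0.07 and its mean -0.005, and the blood cell median was 0.02 and its mean -0.01, with both tests pointing up. The respiratory chain had adjusted p = 0.322 and no called gene among 27.

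Clk/Clk livers on bezafibrate differed from wild-type livers in 1241 genes, 359 higher and 882 lower. Clock genes were prominent: Dbp, a transcription factor driven by CLOCK, was 21.9-fold lower (-4.45, SE 0.5, adjusted p = 1.91e-04). Arntl, which encodes the partner of CLOCK, was higher by 2.66 (SE 0.2, 6.31-fold, adjusted p = 2.11e-05), but a probe set without a suffix gave 0.36 and did not pass. Usp2 (-3.25, SE 0.286), Per2 (-2.16, SE 0.343), Bhlhe40 (-1.90), Per3 (-1.61, SE 0.261) and Wee1 (-1.23) were lower. Nr1d2 was at -0.85, but did not pass without Clk/Clk mouse 1 (-0.58) or in a fit of only these 2 groups. Per1 (0.14), Nr1d1 (-0.10), Cry1 (0.52), Cry2 (-0.12) and Npas2 (0.17) did not pass; Cry1 did, at 0.75, without treated wild-type mouse 3. The clock output list had 8 of 16 lower and none higher (mean -1.04, adjusted p = 8.94e-04; adjusted p = 0.34 with an estimated correlation), and 9 lower when adjusted over the list alone. The positive limb had 3 of 4 higher, Arntl, Clock and Nfil3 (1.06), with a mean of 1.24 (adjusted p = 0.00271; adjusted p = 0.154 with an estimated correlation). The samples were taken at a single time of day, so a change in level and a shift in phase are not separated.

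Outside the clock, DNA replication genes were among the largest differences in Clk/Clk livers. Of 26 cell cycle genes 20 were lower and none higher (mean -1.80, adjusted p = 3.33e-14; adjusted p = 0.28 with an estimated correlation). Mcm5 was at -4.28 (SE 0.445, 19.4-fold), Mcm6 at -3.86, Ccnd1 at -2.28 and Ccna2 at -1.57, and Rrm2 (-3.61), Uhrf1 (-3.48), Fignl1 (-3.86), Zwilch (-3.17) and Shcbp1 (-3.12) also belonged to the largest falls. Fignl1, Zwilch and Shcbp1, as well as the deiodinase Dio1, read under the filter level in Clk/Clk mice, as did the means of Rrm2 (4.78) and Uhrf1 (4.57). The list scores per mouse were -0.15, -0.15 and -0.06 in Clk/Clk mice, against 1.62, 2.20 and 1.20 in treated wild type (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The largest falls further included the peptidase Mme (-4.65, SE 0.23, under the filter level in Clk/Clk mice), the lipase Pnpla3 (-3.24) and Dio1 (-4.23, SE 1.18, adjusted p = 0.0235). Dio1 missed the threshold without Clk/Clk mouse 1 (-4.13) or 3 (-4.07) or treated wild-type mouse 1 (-3.93) or 3 (-4.13). The largest rises were in Pbld1 (4.55, SE 0.882), whose treated wild-type values had an SD of 2.47, Ptger3 (4.09), Npnt (2.46), Cyp2c50 (2.39), Slco1a4 (2.34), Cyp2b10 (2.33), P2ry14 (2.26), Bhmt (2.23), Elovl3 (2.18), Camk1d (2.13) and Pmm1 (2.09). Ptger3 read under the filter level in treated wild type.

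The fatty acid oxidation lists did not pass between Clk/Clk and wild-type mice on bezafibrate. Peroxisomal genes had 1 higher and 2 lower among 31 (adjusted p = 0.564), mitochondrial oxidation genes none among 25 (0.172, or 0.0276 with the mean of a gene's probe sets), and uptake and droplet genes 4 higher and 2 lower among 29 (0.795). The droplet list had a median of 0.03 and a mean of -0.05, with the test pointing up. Pdk4 (0.16), Ehhadh (0.07), Cyp4a14 (0.10), Cpt1a (-0.04) and Angptl4 (0.39) did not pass. Ehhadh read 14.41 in treated wild type and 14.48 in Clk/Clk mice, and Cyp4a14 14.25 and 14.34, where the highest value on any array was 15, so a difference in these 2 genes can be hidden by saturation. Fgf21 was at 0.39, and passed at 0.83 without treated wild-type mouse 3. Peroxisomal calls were Slc25a17 (-1.21), Pecr (0.74) and Nudt7 (-0.77, or -0.46 and not passing without suffix probe sets). Calls in uptake and droplets included Pnpla3, Fabp5 (-2.32), Slc27a1 (1.04) and Plin5 (0.91). Omega-oxidation genes had 1 lower among 11, Cyp4f14 at -1.25 (list adjusted p = 0.082); without treated wild-type mouse 2 there were 4 and the adjusted p was 0.0196, and with no filter it was 0.0369. Lipogenesis, however, had 12 of 25 lower and none higher (mean -0.79, adjusted p = 9.07e-08; adjusted p = 0.154 with an estimated correlation), with Elovl6 at -1.79, Scd2 at -1.74 and Me1 at -1.08. Cholesterol synthesis had 5 of 20 lower (mean -0.49, adjusted p = 0.00499; adjusted p = 0.68 with an estimated correlation), with Pmvk at -1.08 and Tm7sf2 at -0.83. Its call was lost without Clk/Clk mouse 1 (0.0624) or 2 (0.0622). The count of 5 became 3 without Clk/Clk mouse 1, 2 without Clk/Clk mouse 2, 13 without Clk/Clk mouse 3 and 3 without treated wild-type mouse 2. The cholesterol scores overlapped between the groups (exact two-sided permutation p = 0.4).

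Several other lists passed between Clk/Clk and wild-type mice. Amino acid genes had 13 of 30 higher and none lower (mean 0.64, adjusted p = 1.17e-12; adjusted p = 0.154 with an estimated correlation), with Hal at 1.46, Cth at 1.44, Aass at 1.25 and Cps1 at 0.87. Bile acid genes had 5 higher and 1 lower among 22 (mean 0.34, adjusted p = 0.00438; adjusted p = 0.387 with an estimated correlation), and 2 lower when adjusted over the list alone, with Abcb11 at 0.82 and Slco1a1 at -1.99; 2 were also lower without Clk/Clk mouse 2 or treated wild-type mouse 1. Cyp7a1 was at 0.74 and did not pass. Interferon genes had 11 of 19 lower and none higher (mean -1.15, adjusted p = 5.75e-06; adjusted p = 0.639 with an estimated correlation), with Usp18 at -2.39, Ifit3 at -1.88 and Irf7 at -1.85; adjusted over the list alone 12 were lower. Male-predominant genes had 1 higher and 4 lower among 13 (mean -0.56, adjusted p = 0.00271; adjusted p = 0.28 with an estimated correlation), Keg1 at -2.32 among them, and 5 lower when adjusted over the list alone. NRF2 genes had 4 of 20 lower (mean -0.53, adjusted p = 0.00438; adjusted p = 0.666 with an estimated correlation), with Gsta4 at -1.33; adjusted over the list alone 6 were lower. The NRF2 call was lost without Clk/Clk mouse 3 (0.108) or treated wild-type mouse 3 (0.0875), and the count of 4 became 2 without Clk/Clk mouse 2 or 3 or treated wild-type mouse 2 or 3, and 7 without treated wild-type mouse 1. Macrophage markers had 4 of 17 lower (mean -0.42, adjusted p = 0.00166; adjusted p = 0.639 with an estimated correlation), with Clec4f at -0.85 and Cd5l at -0.82; adjusted over the list alone 5 were lower. Their count of 4 became 2 without Clk/Clk mouse 2 or treated wild-type mouse 1, and 8 without treated wild-type mouse 3. Scores per mouse overlapped between the groups for interferon (exact two-sided permutation p = 0.2), NRF2 (0.3) and macrophage genes (0.2).

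The remaining lists did not pass in Clk/Clk mice. Complement genes had 5 of 28 lower, among them C8a (-1.73), C6 (-1.57) and Mbl2 (-1.30), with median 0.01 and mean -0.23 (adjusted p = 0.407). Gluconeogenic genes had 7 higher, such as Irs2 (1.01) and Pck1 (2.08), and 1 lower, Slc2a2 at -2.13, among 17 (0.145); 2 were lower without Clk/Clk mouse 2 or treated wild-type mouse 3. CAR and PXR genes had 5 higher and 2 lower among 20 (0.396), and 6 higher when adjusted over the list alone. Acute phase genes had 4 higher and 1 lower among 28 (0.0844), with Serpina3n at 0.71, and passed without Clk/Clk mouse 2 (0.0352) or treated wild-type mouse 1 (0.00226), with the mean of a gene's probe sets (0.0352) or without suffix probe sets (0.00914). The 1 lower acute phase gene was lost without Clk/Clk mouse 2 or 3, and became 2 without treated wild-type mouse 2 or 3. Lipoprotein genes had Scarb1 higher (1.12) and 3 lower among 20 (0.337), with median 0.08, mean -0.06 and a test pointing up. Growth hormone genes had 1 higher and 2 lower among 12 (0.259). The 1 higher was lost whichever of the 6 arrays was left out, and the 2 lower became 1 without Clk/Clk mouse 1 or 2 and none without treated wild-type mouse 1. Female-predominant genes had 2 higher and 1 lower among 14 (0.259), with 1 higher without treated wild-type mouse 1. Heat shock and cold-inducible genes had the cold-inducible Cirbp higher (0.88) and 4 lower among 14, Hspa1a at -2.30 among them (0.0715). The list passed without Clk/Clk mouse 3 (0.0408) or treated wild-type mouse 2 (0.0444), and the 4 lower became 2 without treated wild-type mouse 3. It also passed with no filter (0.0232), the mean of a gene's probe sets (0.0174), suffix probe sets left out (0.014), quantile normalization (0.0209) or the replicate block (0.0234). ER stress genes had 3 of 21 higher (0.078), with Trib3 at 1.77, and passed without Clk/Clk mouse 2 (0.0198) or with the replicate block (0.0462). The respiratory chain had 1 call among 27, Cs at -0.68 (-0.19 and not passing as the mean of its probe sets), and a list adjusted p of 0.0725; it passed, pointing up, without Clk/Clk mouse 3 (0.0293) or treated wild-type mouse 2 (0.0203) or with the mean of a gene's probe sets (0.00426). Stellate markers had 1 higher and 3 lower among 17 (0.337), with Col3a1 at -1.33; the 1 higher was lost without Clk/Clk mouse 2 or 3 or treated wild-type mouse 1. Adjusted p was 0.231 for endothelium, 0.642 for cholangiocytes (1 lower, kept only without treated wild-type mouse 1, and none when adjusted over the list alone), 0.596 for blood cells (3 lower among 13) and 0.564 for carry-over markers.

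**Figure D2:**
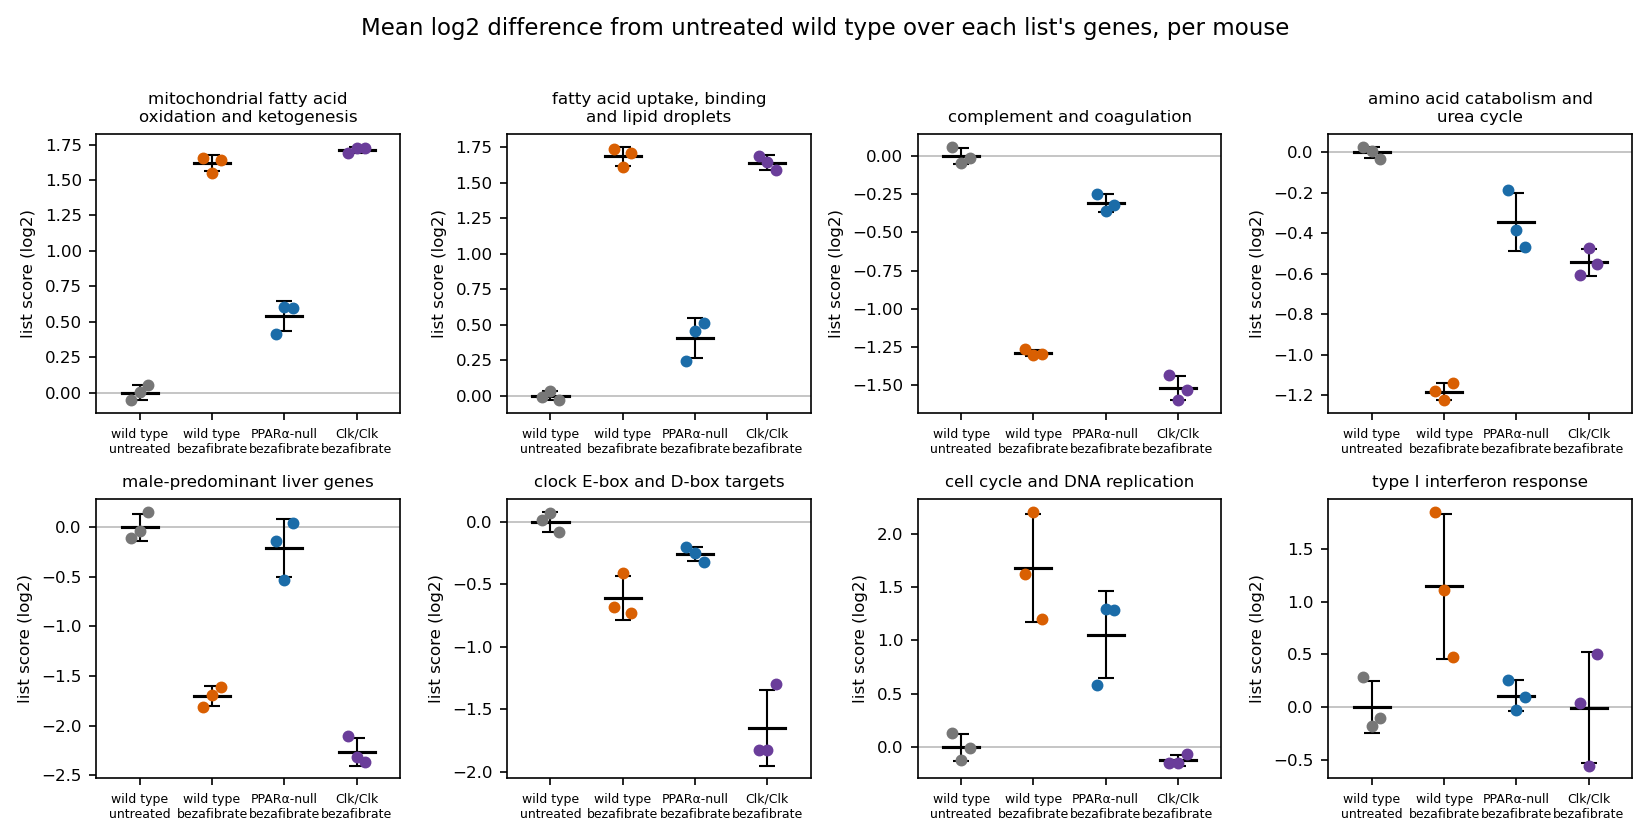
Score per mouse (y axis, mean log2 difference from untreated wild type over a list's genes) for 8 lists in the 4 groups (x axis), one point per mouse, with bars at the group mean and SD (n = 3); the lists were chosen for display after their values were seen. Mitochondrial oxidation scores were 1.69 to 1.73 in Clk/Clk mice and 0.42 to 0.60 in PPARα-null mice, while cell cycle scores were -0.15 to -0.06 and 0.58 to 1.29.

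The joint set, higher with bezafibrate in wild type and lower in both mutants, held 271 genes, 15.6% of those that rose. Its leading members were Ly6d (5.72 with bezafibrate, -5.58 in null, -0.77 in Clk/Clk), Palb2 (3.82, -3.33, -2.74), Mcm5 (3.87, -1.27, -4.28), 4930579G24Rik, Slc39a5 (3.96, -3.80, -1.23), Mcm6, Usp18 (2.76, -2.64, -2.39), Zwilch, Ccnd1 (3.16, -2.21, -2.28), Slfn4 (2.60, -2.55, -2.45), Scd2 (3.25, -2.58, -1.74), Sdr16c5 (2.22, -2.54, -2.69), Trip13, Synpo and Mcm4. Both mutant calls of Slfn4 were lost in fits of only the 2 groups compared, and Slfn4 and Sdr16c5 read under the filter level in both mutants. The null call of Mcm5 was lost without null mouse 1 (-0.77) or treated wild-type mouse 1 (-1.37) or 2 (-0.83), with replicate number as a block (-1.27), array weights (-1.20), robust settings (-1.27) or quantile normalization (-1.25), and in the fit of 2 groups. That of Mcm6 was lost without null mouse 1 (-0.66) or 3 (-1.27) or treated wild-type mouse 1 (-1.21) or 2 (-0.74), with robust settings (-1.13) or quantile normalization (-1.11) and in the fit of 2 groups. That of Mcm4 was lost without null mouse 1 (-0.91) or treated wild-type mouse 2 (-0.90) and in the fit of 2 groups. The Clk/Clk call of Ly6d was lost without Clk/Clk mouse 3 (-0.61) or treated wild-type mouse 2 (-0.62). The mirror set, lower with bezafibrate and higher in both mutants, held 92 genes, 8.71% of those that fell. It was led by Cyp2c50 (-6.84, 6.21, 2.39), Cyp2c54 (-6.65, 5.76, 1.53), Pbld1 (-3.90, 3.61, 4.55), Pck1 (-4.66, 3.28, 2.08) and Slco1a4 (-2.10, 4.95, 2.34), and included Pigr (-4.29, 3.22, 1.01), Hsd3b2, Sult1a1, Sdr9c7 (-4.01, 3.19, 0.59), Slc1a2 (-3.91, 3.14, 0.66), Il6ra, Etnppl, Cyp2b10, Got1 and Oat. The Clk/Clk call of Pigr was lost without Clk/Clk mouse 3 (0.77) or treated wild-type mouse 1 (0.93) or 2 (0.78) and in the fit of 2 groups. Those of Sdr9c7 and Slc1a2 were lost without Clk/Clk mouse 2 (0.57, 0.55) or 3 (0.58, 0.64) or treated wild-type mouse 1 (0.48, 0.53) or 2 (0.56, 0.61), and with the mean of a gene's probe sets (0.58, 0.45). Array weights also ended that of Sdr9c7 (0.58), and the block (0.66) and the fit of 2 groups that of Slc1a2. Of the classical oxidation genes always named, Pdk4, Ehhadh, Cyp4a14 and Fgf21 were lower in null mice and not called in Clk/Clk mice, so none was in the joint set; for Ehhadh and Cyp4a14 the absence carries no weight, since both read near the top of the scale.

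The 3 treated wild-type arrays enter all 3 comparisons, which by itself ties them together. Independent lists of these sizes would share 9.14 genes in the joint set and 1.49 in the mirror. In 20 simulations with mutants set equal to treated wild type both counts averaged 0, but hardly any gene can be called in a mutant there, so these zeros do not bound what the shared arrays contribute. The drug response and the null difference correlated across genes at -0.826, against -0.115 in those simulations, with a covariance of -0.310 against -0.0121. For the Clk/Clk difference the values were -0.326 against -0.109, and -0.0966 against -0.0116. The null and Clk/Clk differences correlated at 0.248, against 0.499, with a covariance of 0.0586 against 0.0113. Genes are not independent replicates, and the 3 treated wild-type arrays cannot be divided into 2 separate sets of 2, so part of the excess may come from the shared arrays. Drug-induced genes lower in Clk/Clk mice numbered 469 (26.9% of those induced, 113 by independent lists), and repressed genes higher there 133 (12.6%, 27.9). In the direction of the drug, 49 induced genes were higher and 82 repressed genes lower in Clk/Clk mice, against 46 and 68.5.

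**Figure D3:**
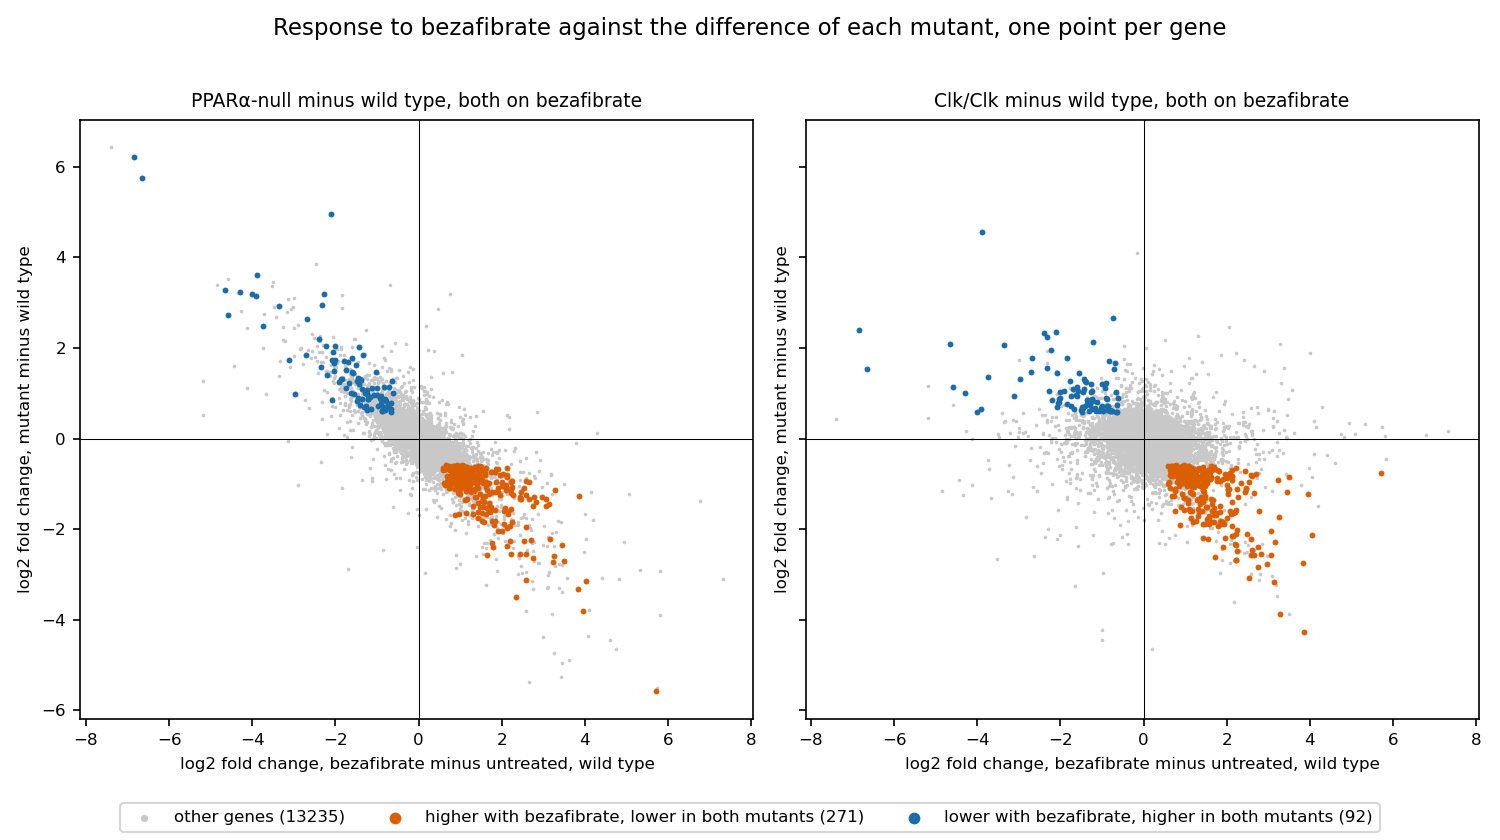
Log2 fold change with bezafibrate in wild type (x axis) against the log2 difference of PPARα-null (left) or Clk/Clk mice (right) from wild type on bezafibrate (y axis), one point per gene, with the 271 joint and 92 mirror genes coloured. The correlation across genes was -0.826 on the left and -0.326 on the right, and the treated wild-type arrays enter both axes.

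Compared with untreated wild type, treated null mice had 538 genes higher and 366 lower, and treated Clk/Clk mice 1447 higher and 1199 lower. Of the 1742 genes induced in wild type 395 (22.7%) were also higher in treated null mice, and 996 (57.2%) in treated Clk/Clk mice, against 68.9 and 185 for independent lists. Of the 1056 repressed genes 222 (21.0%) and 723 (68.5%) were also lower, against 28.4 and 93.1. The untreated wild-type arrays enter both comparisons of each overlap, so part of the excess over independent lists may come from them. No simulation covered these overlaps. In null mice Pdk4 remained 4.22 above untreated wild type, Cyp4a14 3.85, Cd36 2.67 and Ehhadh 1.72, while Fgf21 was at -0.67 and did not pass. Cholesterol synthesis genes were higher in treated null mice for 14 of 20 (mean 1.05, adjusted p = 1.12e-06; adjusted p = 0.5 with an estimated correlation), as was lipogenesis for 12 of 25 (mean 0.76, adjusted p = 5.87e-07; adjusted p = 0.239 with an estimated correlation). Cell cycle genes were higher for 17 of 26 (mean 1.05, adjusted p = 4.54e-07; adjusted p = 0.5 with an estimated correlation). Adjusted over the list alone these counts were 14, 13 and 20. In treated Clk/Clk mice cell cycle genes had 3 calls each way (mean -0.12, adjusted p = 0.427), or 3 higher and 2 lower adjusted over the list alone. Clock output genes were lower for 13 of 16 (mean -1.65, adjusted p = 2.12e-06; adjusted p = 0.0973 with an estimated correlation), and complement genes for 23 of 28 (mean -1.52, adjusted p = 5.22e-18; adjusted p = 0.0131 with an estimated correlation), with the same counts adjusted over the list alone.

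Donor DNA around the altered genes can differ between the lines, so genes near Ppara and Clock were examined. Among the 200 tested genes nearest Ppara, 20 were called between null and wild type (10%, against 13.5% elsewhere; odds ratio 0.711, Fisher's exact two-sided p = 0.174). Among the nearest 100 it was 16% against 13.4% (odds ratio 1.23, exact p = 0.461). Among the 200 nearest Clock, 21 were called between Clk/Clk and wild type (10.5%, against 9.09%; odds ratio 1.17, Fisher's exact two-sided p = 0.458), and among the nearest 100 8% against 9.12% (0.867, exact p = 0.861). The genes near Clock were called more often with bezafibrate (odds ratio 1.43, exact p = 0.028) and between null and wild type (1.52, exact p = 0.0277). Adjusted over the 18 tests of windows and comparisons, each of these was 0.252. The null line derives from another strain crossed with Jcl:ICR, and the number of backcrosses is not given in the sources used here. Strain differences elsewhere in the genome are therefore not separated from genotype in the null comparison. The Clk mutation was bred into ICR, so the same limit may hold in the Clk/Clk comparison.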

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

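The tests of a single mouse, of leukocytes, of a general fall in hepatocyte genes and of macrophages in this part were chosen only after the results were seen. Clk/Clk and PPARα-null mice, both on bezafibrate, were compared directly, and the difference itself was tested. They differed in 2069 genes, 1011 higher and 1058 lower in Clk/Clk mice. Fatty acid lists were higher in Clk/Clk mice than in null mice, with 21 of 31 peroxisomal genes higher and 2 lower (mean 0.995, adjusted p = 0.0129 with an estimated correlation). In mitochondrial oxidation 19 of 25 were higher and none lower (mean 1.17, adjusted p = 0.0422 with an estimated correlation), and in uptake and droplet genes 20 of 29 higher and 2 lower (mean 1.24, adjusted p = 0.0129 with an estimated correlation). Complement genes were lower for 17 of 28 (mean -1.21, adjusted p = 0.0129 with an estimated correlation). Male-predominant genes were lower for 8 of 13 (mean -2.06, adjusted p = 0.0332 with an estimated correlation), and growth hormone genes for 7 of 12 (mean -1.08, adjusted p = 0.0477 with an estimated correlation), with 1 higher in each. Adjusted over the list alone, 22 peroxisomal genes were higher and 9 male-predominant genes lower, and the other counts were the same.

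Probe sets without exactly 1 gene symbol entered none of the comparisons above, yet they carried signal. Of 4456 such probe sets tested with limma, 668 were called with bezafibrate in wild type, 459 between null and wild type and 331 between Clk/Clk and wild type. These are 15%, 10.3% and 7.43%, against 20.6%, 13.4% and 9.13% of named genes.

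Cell cycle genes were lower in Clk/Clk mice than in wild type on bezafibrate. A single treated wild-type mouse as the source is argued against, since the list median was -1.40 or lower with each of the 3 left out in turn. More leukocytes in the treated wild-type livers stay open: their markers had a median change of -0.0267 with bezafibrate, but a small dividing share could hide under a high baseline, so the explanations cannot be told apart. Macrophage markers were lower in Clk/Clk than in treated wild-type mice (mean -0.42, camera adjusted p = 0.00166, and 0.639 with an estimated correlation). Blood cell markers had a mean difference of -0.287 (camera adjusted p = 0.596). Treated wild-type scores lay near the untreated level, at 0.0586 (SD 0.302) for macrophage and -0.0149 (SD 0.212) for blood cell markers. Clk/Clk scores lay below it, at -0.364 and -0.302. These differences therefore do not show more leukocytes in treated wild-type livers. The Clk genotype is named by the design and stays open as well, untested for lack of untreated Clk/Clk mice.

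Male-predominant genes were lower with bezafibrate in wild type. Females among the treated wild-type mice are argued against, since Xist and the median of the Y-linked genes lay within 0.471 of the untreated mean in each treated array. A general fall of hepatocyte genes cannot be told apart from a separate effect. The list's mean lay -0.784 from that of 93 pooled hepatocyte genes (-1.70 against -0.92), with a permutation p of 0.062 over 100000 permutations. Genes were permuted, not mice, and they are not independent, so this p does not measure the spread between mice. The drug itself, named by the design, stays open.

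Interferon genes were higher with bezafibrate in wild type, and treated wild-type mouse 1 had the highest score. Of the 11 genes called, 9 stayed called without it, which argues against that mouse as the only source. The mark for this, at least 9 of the 11, was also set after the results were seen and was only just met. Interferon and macrophage scores deviated together within groups over the 12 livers (Pearson r = 0.819, exact one-sided permutation p = 0.0285; Spearman rho = 0.692, exact one-sided permutation p = 0.0463; r = 0.577 without the 2 farthest livers; 1 relation in the family). More macrophages in some livers may therefore contribute, although macrophage markers as a list did not pass with bezafibrate. The drug as the biological explanation stays open.

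For each comparison the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In each, 1 split, the real one, gave the largest count. Every other split mixes the 2 groups, so a difference between them becomes spread within groups and hardly any gene can be called. The low counts of the other splits are therefore not a chance level, and no conclusion is drawn from them. The real count and the highest other were 2798 and 1 for bezafibrate in wild type, 1827 and 0 for null against wild type, and 1241 and 0 for Clk/Clk against wild type. For treated null and treated Clk/Clk mice against untreated wild type they were 904 and 1, and 2646 and 0. For Clk/Clk against null mice they were 2069 and 0.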

How the results depend on the processing

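No test in this part was chosen after the results were seen. The counts of called list members with an array left out, given here and with the lists, were added only then. The fold threshold moved the counts of called genes most, which follows from its construction. With no fold threshold, a 2-fold threshold and treat against 1.5-fold, in that order, genes higher with bezafibrate in wild type numbered 3710, 810 and 777, and lower 2939, 432 and 416 (1742 and 1056 as reported). For PPARα-null against wild type on bezafibrate they were 2238, 290 and 226 higher, and 2527, 463 and 345 lower (727 and 1100). For Clk/Clk against wild type on bezafibrate they were 1440, 127 and 61 higher, and 1923, 337 and 139 lower (359 and 882). Against untreated wild type, null mice had 1808, 210 and 70 higher and 1167, 114 and 48 lower (538 and 366), and Clk/Clk mice 3359, 630 and 621 higher and 2769, 512 and 500 lower (1447 and 1199). Clk/Clk against null mice had 2523, 446 and 417 higher, and 2508, 476 and 385 lower (1011 and 1058). The joint set held 678 genes with no fold threshold and 80 at 2-fold (271), and the mirror 414 and 31 (92).

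Under the other settings, which varied filter, scaling, probe set choice, fit and weights, no count moved by over 1.5 times, and the joint set ran from 191 to 276. With replicate number as a block, genes higher and lower were 1746 and 1055 with bezafibrate, 729 and 1095 in null mice and 366 and 887 in Clk/Clk mice on bezafibrate, and the joint set held 270. Against untreated wild type the block gave 533 and 367 in null and 1446 and 1199 in Clk/Clk mice, 1014 and 1067 between the mutants, and 95 in the mirror. Residuals of same-number arrays correlated at -0.0924 to 0.125, and the best partner had the same number in 7 of 18 choices. Beyond the list and gene calls named with their results, the block changed 1 other call, Marco in null mice (-0.76).

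With each array left out in turn, genes higher and lower ran from 1698 to 1825 and 1033 to 1098 with bezafibrate, 666 to 755 and 971 to 1208 in null mice, and 294 to 397 and 777 to 1024 in Clk/Clk mice. Against untreated wild type they ran from 428 to 567 and 309 to 386 in null mice, and 1395 to 1496 and 1148 to 1215 in Clk/Clk mice. Between the mutants they ran from 954 to 1064 and 1010 to 1051. The joint set ran from 203 (without null mouse 1) to 379 (without treated wild-type mouse 3), and the mirror from 77 to 93. Of the 271 joint genes reported, between 182 (without treated wild-type mouse 2) and 255 (without untreated mouse 1) stayed in the set. There were 196 left without treated wild-type mouse 1 and 197 without null mouse 1. Some directions of a list with no call gained 1. With bezafibrate these were in cell cycle (without treated mouse 2), cholesterol (untreated 1) and clock output genes (treated 1 or 3, untreated 2). In null mice they were in cell cycle (null 1, treated wild type 1 or 2) and clock output (null 3). In Clk/Clk mice they were in clock output and mitochondrial oxidation (treated wild type 3). With bezafibrate, blood cell markers also gained up to 2 rises, stellate markers up to 1 rise and interferon genes up to 1 fall. Stellate markers gained up to 2 higher in null mice. Cholangiocyte and carry-over markers each gained up to 1 higher in Clk/Clk mice.

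Of the values of named genes, called or not, 4775 stayed on their side of the threshold under other settings, 53 lost the call, 12 gained it and 1 turned; with an array left out these were 2818, 108, 26 and none. The value that turned was Ighm in Clk/Clk mice, at 0.038 without suffix probe sets, which leaves the gene another probe set. Of the list tests, passing or not, 723 stayed on their side, 53 lost the call and 34 gained it; with an array left out 510, 15 and 15. Estimated correlation ended 16 of 19 list calls with bezafibrate, 12 of 16 in null mice and all 11 in Clk/Clk mice. Fry, over the same comparisons, ended 5 list calls and gave 14 others, but it does not compare a list with other genes. Of the 12 tests in other windows near Ppara and Clock, 8 stayed on their side of an unadjusted p of 0.05 and 3 moved above it; none passed after adjustment in any window. The last, near Clock between null and wild type, had an odds ratio of 1 in a window of 400 genes, and the cause was not tested. Odds ratios that did not pass crossed 1 near Ppara with bezafibrate (1.05 to 0.881), in null (0.711 to 1.23) and in Clk/Clk mice (0.865 to 1.23), and near Clock in Clk/Clk mice (1.17 to 0.867). Signal near background limits the folds of genes such as Hao2, Abcd2, Mme and Ptger3, whose lower group read under the filter level.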
